A study of Mus musculus with 12 samples.

How the data were processed

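Sorted GFP+ cells and CD11b+ phagocytes from RasV12 brain tumors and from control cerebellum were profiled by RNA sequencing in 12 libraries, 4 groups of 3. Per the labels' protocols, RNA was isolated with Sepazol, cDNA was made with a SMARTer low-input kit and libraries with Nextera XT, a route that amplifies small amounts of RNA and does not mark strand, so reads of a gene and of an antisense or overlapping partner cannot be told apart. Per the submitters' processing notes, bcl2fastq 2.17.1.14, HISAT2 2.1.0, featureCounts, Subread 1.6.2 and DESeq2 1.20.0 were used with genome build GRCm38.p6; which of them made which value is not given in the sources used here. Cell numbers and sort gates are not given in the sources used here.

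The authors deposited a table of normalized counts per gene, used here as a signal divided by a factor per library, and a table of FPKM values. Both deposited tables hold 54547 genes. FPKM divided by the normalized count was nearly the same in every library for a gene (median CV 0.16% over 1663 genes), so both tables carry the same scaling between libraries. The deposited normalized counts were whole multiples of 1 step per library for at least 99.99% of values (tolerance 0.05), which gave whole reads and the read totals stated with the results. At this depth 1 read was worth 0.358 to 5.54 normalized counts, the most in RasV12 CD11b+ 1 and 2, where a gene with few reads is measured coarsely. For RasV12 GFP+ 1 and 3 the step needed a finer search over higher values.

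Among the deposited genes, 1102 shared their symbol with another gene. Gene IDs matched GENCODE annotation of GRCm38 for 98.3% of genes, which gave coordinates, exon lengths and gene types. Genes with a normalized count of at least 10 in at least 3 libraries were tested, 29835 in all. The main test was limma-trend (limma 3.58.1, R 4.3.3) on log2(normalized count + 1), with 1 mean per group over all 12 libraries and Benjamini-Hochberg adjustment at 0.05. The 5 comparisons were RasV12 against control in GFP+ and in CD11b+ cells, CD11b+ against GFP+ cells in tumors and in controls, and the difference of the RasV12 effects. The 26 gene lists, 15 of pathways and quality and 11 of cell types, were tested with camera at its preset correlation of 0.01 and again with an estimated correlation. Camera sets the members of a list against all other tested genes, so a list can test lower without a fall of its members. Some genes stand in several lists.

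Groups, tests, gene lists, the naming rule and most alternatives were fixed before the data were examined. The rule named the 10 higher and 10 lower genes with the largest change (5 and 5 in the other comparisons) that passed, had a mean of at least 100 in the higher group, did not overlap between groups and had no predicted or clone name. It also named up to 4 members of each list with the smallest adjusted p, of which the text gives a selection, and Hras, Nras, Msi1, Itgam and Ptprc. Some genes that the rule named are not reported here. Clone names of other forms than the rule spelled out, such as number-only names, were passed over too, a choice made after they were seen. That passed over 7 higher and 3 lower genes in CD11b+ cells and 1 in the difference of effects.

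A fold against a group without reads was computed against a floor of 3 reads over the group, and one against 1 to 3 reads was given as a ratio with a 95% interval from an exact binomial test. Alternatives were the FPKM table, upper-quartile and quantile scaling, other pseudocounts and filters, robust variance, array weights, fits of 6 libraries, the replicate number as a block, edgeR 4.0.16 quasi-likelihood with TMM and DESeq2 1.42.0 on the recovered reads, and leaving out each library. Chosen after seeing the data were background subtraction, sex as a covariate, leaving out libraries with background or low depth, and leaving out receptor and clone-named genes. Background per library was the count per kb of receptor and TEC genes in classes of GC content, multiplied by exon length. It came to 50.6 to 67.3% of nuclear counts in RasV12 CD11b+ libraries, 44.8% in Control CD11b+ 2, 7.9 and 8.8% in Control CD11b+ 1 and 3 and 2.3 to 6.4% in GFP+ libraries. A version that left out the genes with the highest values among these was computed before the one used and gave 24.1 to 32.0%, 24.3%, 3.7 and 4.1%, and 0.0 to 2.1%. Levels and main tests are without subtraction.

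The pipeline was tested on simulated data with known changes before use. At 4-fold, 16-fold and 64-fold it recovered 1.5%, 32.8% and 66.7% of changed genes in the GFP+ comparison, over 26455 genes with 1 false call. In the CD11b+ comparison it recovered 4.5%, 23.9% and 56.1%, over 27163 genes with 42 false calls. For the difference of effects it recovered 0%, 1.5% and 12.1%, over 27303 genes. Genes with low mean counts were not among those changed. The median SE of a log2 fold change was 1.37, so changes of a few fold were mostly not detectable. Tables were made with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6 and figures with matplotlib 3.10.9. Raw reads were not analysed here.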

Results

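RNA was sequenced from cells sorted out of mouse brain, in 4 groups of 3 libraries each. GFP+ cells and CD11b+ phagocytes came from brain tumors of mice that carried Msi1-CreER, an inducible Cre recombinase under control of the Musashi-1 gene of neural stem and progenitor cells, together with RasV12, an oncogenic form of Ras. The same sorted populations came from the cerebellum of control mice that carried Msi1-CreER and a GFP gene. CD11b is the integrin encoded by Itgam and marks microglia, macrophages, monocytes and neutrophils. The design asks how the RasV12 tumor cells and the phagocytes of the tumor differ from their counterparts in control tissue. RasV12 cells came from tumors and control cells from cerebellum, so tissue and genotype differ together in these comparisons. The labels do not say that replicates came from separate animals, so p-values measure the spread between these libraries, which may be partly technical.

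Read totals recovered from the deposited values were 18519240 to 32624399 in Control GFP+, 21227344 to 34432725 in RasV12 GFP+ and 7883870 to 34601205 in Control CD11b+ libraries. In RasV12 CD11b+ they were 3642570, 2951629 and 23589310 for replicates 1, 2 and 3. Replicates of a group correlated over log2 values with r of 0.812 to 0.843 in Control GFP+, 0.842 to 0.880 in RasV12 GFP+, 0.657 to 0.887 in Control CD11b+ and 0.512 to 0.537 in RasV12 CD11b+ libraries. These correlations are across genes, which are not independent replicates. Values below are mean normalized counts ± SD over 3 libraries, and log2 fold changes ± SE on the log2(normalized count + 1) scale. This scale can understate the change of low genes. It can also overstate a fall in RasV12 CD11b+ 1 and 2, where each read was worth 4.456 and 5.538 normalized counts. A library without reads is set far below that worth. Intervals and floors given for genes with few reads cover counting error only.

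In RasV12 GFP+ cells the lists of MAPK/ERK output, cell cycle, p53 target and Cdkn, matrix, and cytokine and chemokine genes were higher than in control GFP+ cells, and those of oligodendrocytes, neurons and astrocytes were lower, with the counts and tests given for each list. Spp1, which encodes the secreted phosphoprotein osteopontin (chromosome 5, 104435118 to 104441050, GRCm38), stood at 233603 ± 107368 in RasV12 and 345.5 ± 183.0 in control GFP+ cells, a log2 fold change of 9.48 ± 0.68 (adjusted p = 1.21e-05). Cdkn2b, an inhibitor of the cyclin D kinases (chromosome 4, 89306299 to 89311039), rose from 32.5 ± 27.2 to 10988 ± 1293 (log2 fold change 9.02 ± 1.07, adjusted p = 0.000359). Mbp, a major myelin protein gene (chromosome 18, 82475146 to 82585637), fell from 719818 ± 294912 to 5426 ± 6086 (log2 fold change -7.87 ± 0.76, adjusted p = 8.74e-05). Of 29835 genes tested, 1235 were higher and 792 lower in RasV12 GFP+ cells.

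The 10 higher genes with the largest change under the naming rule were Gal, Areg, Hpse, Psrc1, Chrdl1, Plau, Fam111a, Angpt2, Dhh and Gdf15. Gal, the gene of the neuropeptide galanin (chromosome 19, 3409915 to 3414544), had 12643 ± 4162 normalized counts in RasV12 and 2.2 ± 1.1 in control GFP+ cells. Areg, a ligand of the EGF receptor, was 7676-fold higher (95% counting interval 2626 to 37220, from 3 reads in the control group). Plau, the urokinase plasminogen activator, was 7158-fold higher (1284 to 282700). Hpse, which encodes heparanase, had no read in control GFP+ cells and was at least 3066-fold higher, against a floor of 3 reads over the group. Dhh, a hedgehog ligand, was at least 1995-fold higher and Fam111a at least 2063-fold higher by the same floor. Angpt2, an angiopoietin, rose from 2.8 ± 3.7 to 4468 ± 561, and Gdf15, a stress-induced cytokine, was 3040-fold higher (1040 to 14740). Psrc1 was 5789-fold higher (1602 to 47810) and Chrdl1, a BMP antagonist, 8236-fold higher (1478 to 325300).

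The 10 lower genes with the largest change were Mog, Ttr, Mal, Car8, Tspan2, Gjb1, Hapln2, Ntsr2, Fa2h and Slco4a1. Mog, a myelin surface glycoprotein gene (chromosome 17, 37010743 to 37023398), fell from 16051 ± 866 to 1.4 ± 1.4. Mal, another myelin membrane gene, fell from 23821 ± 7154 to 4.9 ± 4.3, Tspan2 from 15427 ± 4712 to 12.1 ± 12.1, and Fa2h, the enzyme that hydroxylates myelin lipids, from 4168 ± 1105 to 4.4 ± 6.6. Ttr, the thyroid hormone carrier made by choroid plexus, fell from 64786 ± 44600 to 9.1 ± 5.0, and the Purkinje cell gene Car8 from 10704 ± 2972 to 8.1 ± 10.8. Ntsr2, a neurotensin receptor of astrocytes, fell from 5907 ± 2061 to 8.6 ± 14.2. Hapln2 had no read in RasV12 GFP+ cells and was at least 3539-fold lower. Gjb1, a connexin gene, was 12850-fold lower (2305 to 507500) and Slco4a1 10900-fold lower (1956 to 430800).

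**Figure D1:**
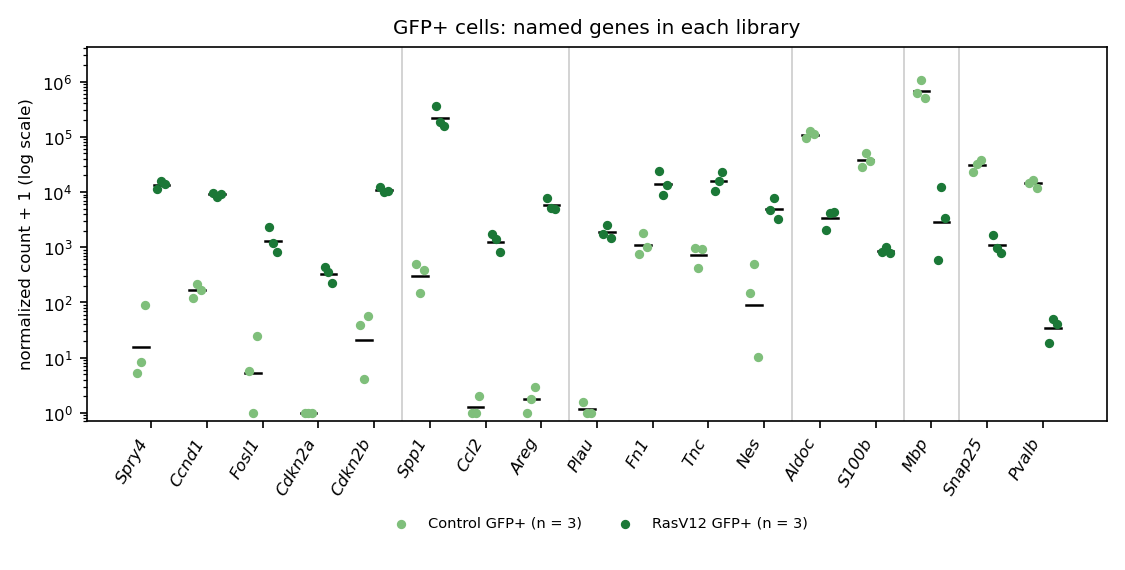
Normalized count + 1 on a log axis for 17 named genes in the GFP+ libraries. Points are libraries, light green for control and dark green for RasV12, and bars are means of the log values; all 3 RasV12 libraries lay above all control libraries for Spp1, Cdkn2b, Spry4 and Plau, and below them for Aldoc, Mbp and Pvalb.

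Genes downstream of Ras rose as a group. Of 17 MAPK/ERK output genes tested, 6 rose, 1 fell and 10 did not pass (14 higher and 1 lower adjusted over the list alone; median log2 fold change 3.74; camera adjusted p = 2.3e-06). Spry4, a feedback inhibitor of the pathway, rose from 34 ± 49 to 13573 ± 2154, Ccnd1, the gene of cyclin D1, from 168.5 ± 47.9 to 9033 ± 865, and Fosl1, an AP-1 subunit, from 9.4 ± 12.4 to 1452 ± 796. Hras and Nras themselves did not pass the test, with log2 fold changes of 0.00 ± 0.89 and -0.40 ± 0.47 (adjusted p = 1 and 0.756). These are endogenous Ras genes, and reads of the transgene were not analysed here. Msi1, the gene whose promoter drives the Cre, stood at 58.7 ± 34.2 in control and 32.9 ± 12.4 in RasV12 GFP+ cells (adjusted p = 0.938).

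Of 29 cell cycle genes, 11 rose and 18 did not pass (18 higher adjusted over the list alone; median 4.33; camera adjusted p = 7.2e-09). Cdk1, the mitotic kinase, rose from 10.4 ± 18.1 to 343.5 ± 206.5 (past the threshold in 18 of 22 alternatives, with adjusted p = 0.000461 to 0.136 over them), and Cdc20, an activator of the anaphase-promoting complex, was at least 397.5-fold higher. Of 14 p53 target and Cdkn genes, 8 rose and 6 did not pass (13 higher adjusted over the list alone; median 3.06; camera adjusted p = 1.4e-09). Besides Cdkn2b, Cdkn2a, the locus of p16 and p19Arf, was at least 431.8-fold higher, and Pmaip1, which encodes the pro-apoptotic protein Noxa, rose from 16.4 ± 27.0 to 3190 ± 986.

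Of 20 matrix and mesenchymal genes, 9 rose and 11 did not pass (11 higher and 1 lower adjusted over the list alone; median 3.07; camera adjusted p = 0.00013). Fn1, the gene of fibronectin, rose from 1180 ± 546 to 15465 ± 7867, Tnc, the gene of tenascin C, from 767.2 ± 304.8 to 16505 ± 6407, and Timp1, a metalloproteinase inhibitor, from 107.7 ± 27.1 to 16761 ± 7551. Of 22 cytokine and chemokine genes, 9 rose and 13 did not pass (12 higher adjusted over the list alone; median 3.35, or 3.47 with unread groups at their bound; camera adjusted p = 4.1e-09). Ccl2, a monocyte attractant, was 4914-fold higher (881.8 to 194100), and Ptgs2, the gene of the inducible cyclooxygenase, 3350-fold higher (927.1 to 27660).

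Antigen presentation genes had 2 of 15 higher (5 over the list alone) with B2m, the light chain of class I molecules, going from 4382 ± 434 to 11677 ± 2605 (camera adjusted p = 0.0048; adjusted p = 0.27 with an estimated correlation). Pro-inflammatory macrophage genes had 4 of 19 higher (4 over the list alone), among them Ptgs2 and the T-cell costimulator Cd80, at least 276.6-fold higher (camera adjusted p = 0.0048; adjusted p = 0.079 with an estimated correlation). Disease-associated microglia genes had 4 of 18 higher and 1 lower (8 and 1 over the list alone). There Spp1 rose while Apoe, a lipid carrier abundant in astrocytes, fell from 140971 ± 25683 to 14057 ± 4372 (camera adjusted p = 0.0081; adjusted p = 0.27 with an estimated correlation). Dissociation and immediate early genes had 1 of 12 higher (3 over the list alone; camera adjusted p = 0.018; adjusted p = 0.51 with an estimated correlation).

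The remaining pathway lists did not pass the list test in GFP+ cells. Counts of members higher and lower were 2 and 0 of 16 for interferon response, where Ifitm3 rose from 1279 ± 658 to 11030 ± 2112, and 4 and 1 of 26 for phagocytosis and engulfment. In that list Itgb2, the beta chain partner of CD11b, was at least 188.1-fold higher, and Sirpa, an inhibitory receptor for CD47, fell from 5109 ± 588 to 724.6 ± 210.3. Alternative macrophage activation had 3 of 15 higher, among them Tgfb1 at 66.6 ± 51.9 and 588.2 ± 90.4. Immune checkpoint had 2 higher and 1 lower of 12, with Cd274, which encodes PD-L1, at least 236.4-fold higher. Hypoxia and glycolysis had 2 higher and 3 lower of 20. The lactate transporter Slc16a3 was at least 159.1-fold higher there, and the glucose transporter Slc2a1 fell from 9774 ± 5283 to 643.7 ± 179.0. Lipid handling and cholesterol had 1 higher and 1 lower of 16, with the synthesis enzyme Hmgcs1 falling from 5180 ± 1567 to 1245 ± 704. Adjusted over the list alone, these lists had 3 and 0, 9 and 3, 3 and 0, 2 and 1, 3 and 5, and 1 and 1 members higher and lower, with camera adjusted p = 0.18, 0.087, 0.12, 0.9, 0.34 and 0.9. For hypoxia and glycolysis and for lipid handling the median was below 0 (-0.31 and -0.11, as was the sign of the test) and the mean above it (0.37 and 0.71), and the medians were 0.23 and 0.43 after upper-quartile rescaling.

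Several lists of cell type markers were lower in RasV12 GFP+ cells. Of 12 oligodendrocyte lineage genes 9 fell and none rose (9 lower over the list alone; median -8.12; camera adjusted p = 3.2e-21), Mog and Mbp among them. Of 16 neuron genes 11 fell and none rose (14 lower over the list alone; median -5.37; camera adjusted p = 1.9e-22), with the synaptic gene Snap25 going from 31394 ± 7372 to 1148 ± 484 and the Purkinje and interneuron gene Pvalb from 14410 ± 2426 to 35.8 ± 16.4. Of 15 astrocyte and Bergmann glia genes 6 fell and none rose (9 lower over the list alone; median -2.63; camera adjusted p = 2.2e-15), with Aldoc going from 110215 ± 16580 to 3534 ± 1254 and S100b from 38684 ± 12023 to 870.9 ± 132.1. Endothelial and pericyte genes had 5 lower of 9 (5 over the list alone; median -2.84; camera adjusted p = 1.4e-05), with the tight junction gene Cldn5 falling from 4349 ± 717 to 182.1 ± 160.9. Erythroid genes had 4 lower of 5 (4 over the list alone; median -9.18; camera adjusted p = 5.9e-09), with Hbb-bs at 179872 ± 226389 in control GFP+ cells. Mitochondrially encoded transcripts moved the same way, from 24.4% ± 5.40 of reads in Control GFP+ to 2.01% ± 0.558 in RasV12 GFP+ libraries, and 23 of 31 such genes were lower. Among them the ribosomal RNA gene mt-Rnr2, chosen after its values were seen, went from 1730208 ± 541657 to 43821 ± 12017, while the nuclear 18S gene Rn18s-rs5 had 24546 ± 4883 and 14295 ± 5116 (adjusted p = 0.181).

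Neural stem and progenitor genes had 2 higher and 13 not passing of 15 (2 higher over the list alone; camera adjusted p = 0.36), with the intermediate filament gene Nes rising from 219.0 ± 253.3 to 5202 ± 2312. The myeloid and lymphoid lists did not pass the list test in GFP+ cells. Itgam was at 0.0 in control and 0.2 ± 0.3 in RasV12 GFP+ cells, and Ptprc, the pan-leukocyte gene of CD45, at 33.2 ± 53.2 and 107.2 ± 76.1 (adjusted p = 0.976 and 0.133). Members higher and lower were 2 and 1 of 16 for homeostatic microglia, 4 and 1 of 15 for monocyte and recruited macrophage, 1 and 1 of 12 for pan-myeloid, and none of 11 and of 10 for neutrophil and lymphocyte genes. Adjusted over the list alone they were 3 and 1, 4 and 3, 4 and 1, and none, with camera adjusted p = 0.45, 0.72, 0.092, 0.99 and 0.76. The neutrophil median was 0.42 while its test pointed down, and it was -0.76 after quantile normalization, which also turned the monocyte and lymphocyte medians to -0.15 and -0.49 and that of immune checkpoint to -0.25. Cd68, a lysosomal glycoprotein gene, rose from 34.4 ± 58.7 to 1237 ± 328, and Itga4, an integrin gene, was 1252-fold higher (224.5 to 49480).

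These counts come from limma-trend with Benjamini-Hochberg adjustment, and 10 of the 14 lists that passed, 5 higher and 5 lower, also held with an estimated correlation. The higher share of the 2027 calls was 60.9%, against 76.2% after upper-quartile rescaling and 49.3% after quantile normalization, and the median log2 fold change of all genes was 0.56, 0.91 and -0.12 under these scalings. Calls numbered 1324 without Control GFP+ 2, and 1005, 1040 and 1084 without RasV12 GFP+ 1, 2 and 3. Of 55 named genes called, B2m, Cldn5, Hmgcs1, Nes, Slc16a3, Slc2a1 and Tgfb1 lost the call without at least 1 of the libraries, all 7 of them without RasV12 GFP+ 2, with adjusted p of up to 0.118 where lost. With background subtracted 8 of the 55 lost it, namely B2m, Ccnd1, Cdk1, Hmgcs1, Nes, Slc16a3, Slc2a1 and Snap25 (adjusted p = 0.0508 to 0.335), and after rescaling as well B2m passed and Cdc20 did not (adjusted p = 0.0565). For Ccnd1, Cdk1 and Snap25 the log2 fold changes of 5.77 ± 0.67, 6.60 ± 1.22 and -4.82 ± 0.46 were then 6.02 ± 1.82, 6.71 ± 2.08 and -4.86 ± 1.65 (adjusted p = 0.0958, 0.107 and 0.149), so a larger standard error, which the model takes from all 4 groups, ended these calls. Cdk1 and Cd68 did not pass with edgeR (adjusted p = 0.0916 and 0.0646) or in the fit of the 6 GFP+ libraries alone (adjusted p = 0.0734 and 0.0723).

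In CD11b+ cells, the lists of homeostatic microglia, phagocytosis and neutrophil genes were lower in the tumor by the preset test, with 2 of 16, 5 of 26 and 3 of 11 members past the threshold. None of these list calls held with an estimated correlation (adjusted p = 0.069, 0.069 and 0.087 with an estimated correlation). Sirpa, the CD47 receptor gene (chromosome 2, 129592835 to 129632228), fell from 36954 ± 21079 in control to 2946 ± 803 in RasV12 CD11b+ cells (log2 fold change -3.49 ± 0.43, adjusted p = 0.00158). P2ry13, a purinergic receptor gene of microglia (chromosome 3, 59207892 to 59210882), fell from 21477 ± 14844 to 1385 ± 1005 (-3.83 ± 1.0, adjusted p = 0.0434). It was past the threshold in 12 of 24 alternatives, with adjusted p = 0.00683 to 0.358 over them, and not without Control CD11b+ 1 or 3 or RasV12 CD11b+ 1 or 2 (adjusted p = 0.184, 0.212, 0.108 and 0.103). Spp1 rose from 875.9 ± 816.0 to 5027 ± 2604 (2.83 ± 0.68, adjusted p = 0.0315), in 16 of 24 alternatives (adjusted p = 0.00902 to 0.306 over them), and did not pass without Control CD11b+ 3 or RasV12 CD11b+ 1 or 3 (adjusted p = 0.141, 0.0797 and 0.0721). The 24 alternatives hold the same fit without Control CD11b+ 2 under both names, as a left-out library and for its background. Of the 29835 genes tested, 886 were higher and 713 lower. Of the 886, 471 had predicted or clone names and 67 were olfactory or vomeronasal receptor genes, against 12130 and 1095 of all 29835 tested.

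RasV12 CD11b+ libraries stood apart from the others in reads on genes that brain cells are not known to use. Olfactory receptor genes had 90.1 ± 20.7 normalized counts per kb of exon in RasV12 CD11b+, 18.8 ± 22.7 in Control CD11b+, 1.77 ± 0.71 in Control GFP+ and 3.10 ± 1.01 in RasV12 GFP+ libraries. Control CD11b+ 2 was at 45.02 and Control CD11b+ 1 and 3 were at 5.61 and 5.81. Mitochondrially encoded transcripts took 15.1% ± 2.27 of reads in RasV12 CD11b+ and 1.5% ± 0.967 in Control CD11b+ libraries, and 28 of 31 such genes were higher. A background estimated from receptor genes and genes of the annotation class TEC came to 50.6 to 67.3% of nuclear counts in RasV12 CD11b+ libraries and 44.8% in Control CD11b+ 2, or 24.1 to 32.0% and 24.3% with the highest of these genes left out. It is included in the levels given for CD11b+ cells. Rn18s-rs5 rose from 6762 ± 3537 to 143061 ± 19612 (adjusted p = 0.000078).

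**Figure D2:**
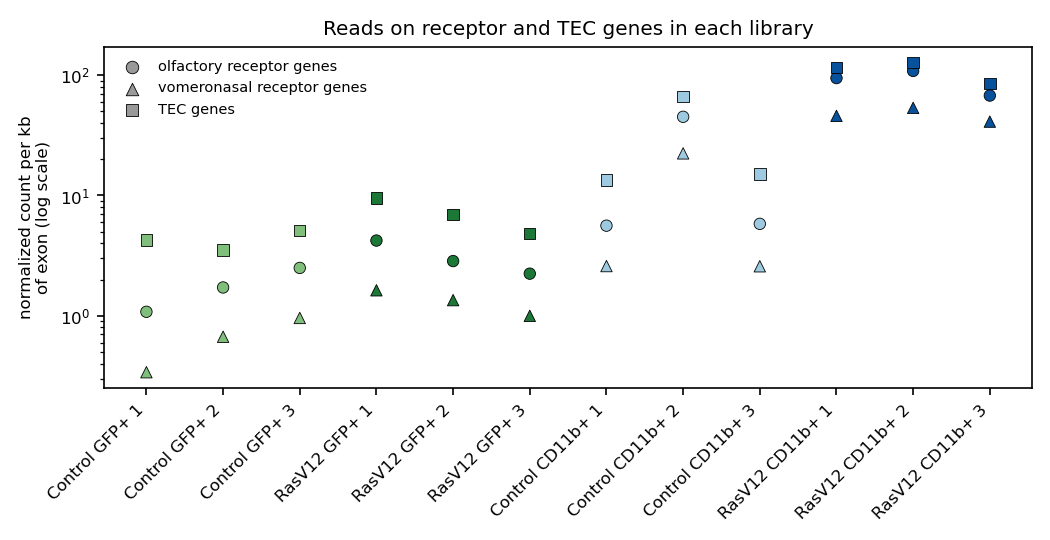
Normalized counts per kb of exon, on a log axis, summed over olfactory receptor genes, vomeronasal receptor genes and genes of the annotation class TEC, transcribed regions of unknown coding status. Points are 1 gene class in 1 library, colored by group; olfactory receptor genes lay between 67.6 and 108.3 in the RasV12 CD11b+ libraries, at 45.02 in Control CD11b+ 2 and between 1.08 and 4.22 in all GFP+ libraries.

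The 10 higher genes with the largest change under the naming rule were Saa3, Crp, Mrgpra3, Aebp1, Peak1os, Tex24, Olfr1105, Olfr66, Pkdrej and Olfr168. Saa3, an acute-phase serum amyloid gene (chromosome 7, 46711998 to 46715700), rose from 4.7 ± 5.1 to 2232 ± 2174. Crp, another acute-phase gene, was 1506-fold higher (269.4 to 59560), Mrgpra3, an itch receptor gene of sensory neurons, 1235-fold higher (220.8 to 48860), and Peak1os 216.1-fold higher (73.28 to 1054). Aebp1 and the testis gene Tex24 had no read in control CD11b+ cells and were at least 409.0-fold and 253.7-fold higher. The olfactory receptor genes Olfr1105, Olfr66 and Olfr168 rose to 582.7 ± 463.8, 511.4 ± 267.3 and 285.9 ± 144.3, and Pkdrej, a sperm gene, to 671.5 ± 220.3. Reads of receptor genes can be shared with close paralogs, so single members are uncertain. After background subtraction Crp, Peak1os, Olfr1105, Olfr66 and Olfr168 no longer had 3 libraries at the count minimum and were not tested. Saa3, Mrgpra3, Aebp1, Tex24 and Pkdrej still passed, with log2 fold changes of 10.31, 8.08, 7.05, 5.77 and 7.63. Since a testis and a sperm gene were among them, passing after subtraction does not by itself tell expression from background.

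The 10 lower genes with the largest change were Tmem167b, Cd1d1, Inafm1, Lcn2, Bag5, Ngp, Gipc1, Ecscr, Efnb1 and Chst7. Cd1d1, which presents lipid antigens (chromosome 3, 86995834 to 86999441), had 477.6 ± 89.0 in control and no read in RasV12 CD11b+ cells, and was at least 343.3-fold lower. Tmem167b and Efnb1 were at least 438.5-fold and 216.1-fold lower. Inafm1 was 1741-fold lower (312.4 to 68800) and the co-chaperone Bag5 726.1-fold lower (248.3 to 3522). Lcn2 and Ngp, both products of neutrophil granules, fell from 1700 ± 807 to 20 ± 34.7 and from 9546 ± 4035 to 107.7 ± 98.7. Gipc1 fell from 651.4 ± 499.9 to 1.0 ± 1.7, Ecscr from 1860 ± 961 to 84.7 ± 146.6 and Chst7 from 846.8 ± 485.6 to 10 ± 17.3. The log2 fold change of Ecscr was -8.05, and -4.46 with DESeq2 on the recovered reads (adjusted p = 0.0891). Ranks by log2 fold change are thus uncertain for genes with unread libraries.

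Homeostatic microglia genes were lower as a group in the tumor. Of 16, 2 fell and 14 did not pass (7 lower over the list alone), with a median log2 fold change of -2.94 (camera adjusted p = 4.4e-08; adjusted p = 0.069 with an estimated correlation). Besides P2ry13, Sparc fell from 61399 ± 30678 to 13977 ± 3299. Gpr34 stood at 29631 ± 13480 in control and 2415 ± 342 in RasV12 cells, and Tgfbr1, a receptor of TGF-beta, at 26656 ± 7010 and 3614 ± 1304 (adjusted p = 0.0583 and 0.079). Csf1r, the receptor that microglia depend on, stood at 122158 ± 81426 and 16349 ± 4226 (adjusted p = 0.09). Pan-myeloid genes had none of 12 past the threshold by gene or over the list alone, with a median of -1.61 (camera adjusted p = 0.0064; adjusted p = 0.22 with an estimated correlation). Among them Laptm5 had 54858 ± 34597 and 10851 ± 4314, and Itgam, the sorted marker, 5117 ± 126 and 1936 ± 1009 (adjusted p = 0.204 and 0.269). Ptprc had 7844 ± 1723 and 6469 ± 2010 (adjusted p = 0.885).

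Phagocytosis and engulfment genes had 5 lower of 26 and none higher (6 lower over the list alone; median -1.56; camera adjusted p = 6.3e-07; adjusted p = 0.069 with an estimated correlation). Besides Sirpa, the apoptotic cell receptor Mertk fell from 10899 ± 3153 to 2253 ± 653, the Fc receptor Fcgr3 from 32832 ± 19509 to 3635 ± 1020, and Elmo1, an activator of Rac in engulfment, from 9028 ± 3332 to 2836 ± 792. Neutrophil genes had 3 lower of 11 (6 over the list alone; median -3.55; camera adjusted p = 4.7e-06; adjusted p = 0.087 with an estimated correlation). Camp, the gene of cathelicidin, fell from 1841 ± 505 to 15.5 ± 16.7 and S100a9, a calprotectin subunit, from 6510 ± 1627 to 574.4 ± 318.1. Camp was past the threshold in 23 of 24 alternatives and S100a9, with adjusted p = 0.0486 by limma, in 10 of 24. Monocyte and recruited macrophage genes had 1 lower of 15, Ifitm6 (1 over the list alone; camera adjusted p = 0.33). Ifitm6 had adjusted p = 0.0489 by limma and was past the threshold in 11 of 24 alternatives.

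Further lists that passed the preset test in CD11b+ cells lost it with an estimated correlation. The test sets a list against all other tested genes, so a call with few changed members need not be a fall of its genes. MAPK/ERK output had none of 17 past the threshold (2 higher and 4 lower over the list alone; camera adjusted p = 0.032; adjusted p = 0.22 with an estimated correlation). The p53 target and Cdkn list had 1 lower of 14 (2 over the list alone), with the same camera adjusted p = 0.032 and the same adjusted p = 0.22 with an estimated correlation. Hypoxia and glycolysis had 3 lower of 20, with Slc2a1 falling from 1568 ± 845 to 152.9 ± 194.3 (1 higher and 4 lower over the list alone; camera adjusted p = 0.018; adjusted p = 0.099 with an estimated correlation). Antigen presentation had 1 lower of 15, B2m, from 31569 ± 12262 to 12331 ± 6083 (1 over the list alone; camera adjusted p = 0.048; adjusted p = 0.44 with an estimated correlation). Disease-associated microglia genes had 1 higher, Spp1, and 1 lower, Cd9, from 11763 ± 7837.4 to 1342 ± 502, of 18 (1 and 2 over the list alone; camera adjusted p = 0.032; adjusted p = 0.38 with an estimated correlation).

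Markers of other brain cells were mixed in CD11b+ libraries. Endothelial and pericyte genes had 1 higher of 9 (4 over the list alone; median 2.43; camera adjusted p = 0.017; adjusted p = 0.22 with an estimated correlation), with the VEGF receptor Kdr rising from 199.5 ± 126.7 to 1849 ± 482. Astrocyte and Bergmann glia genes had 3 higher and 3 lower of 15 (3 and 5 over the list alone; camera adjusted p = 0.33), with Gfap going from 504.4 ± 305.3 to 3749 ± 1246 and the connexin Gja1 from 565.8 ± 432.8 to 1869 ± 236. Oligodendrocyte lineage genes had 1 of 12 higher, the precursor receptor Pdgfra, from 31.5 ± 19.9 to 460.7 ± 184.0, and 1 lower (1 and 2 over the list alone; camera adjusted p = 0.18). After background subtraction Pdgfra did not pass, with a log2 fold change of 2.44 ± 1.90 against 3.93 ± 0.90 before (adjusted p = 0.415), and it passed in 15 of 24 alternatives (adjusted p = 8.36e-05 to 0.415 over them). Neuron genes had 1 of 16 higher, Syt1, from 482.3 ± 474.4 to 3220 ± 1529, and 1 lower, Pcp2, from 128.7 ± 34.4 to 9.2 ± 16 (2 and 1 over the list alone; camera adjusted p = 0.82). Neural stem and progenitor genes had 1 of 15 higher, Fabp7, from 31.7 ± 27.5 to 410.3 ± 181.7 (1 over the list alone; camera adjusted p = 0.59). Lymphocyte genes had 1 of 10 lower, the B-cell gene Cd79b, from 802.1 ± 179.9 to 55.9 ± 92.1 (2 higher and 1 lower over the list alone; camera adjusted p = 0.66), and erythroid genes none of 5 (camera adjusted p = 0.81). Among the CD11b+ libraries, those of RasV12 had the most receptor-gene and mitochondrial reads. The medians of the astrocyte, neuron and monocyte lists were 0.10, 0.05 and 0.31 while their tests pointed down. Camera compares a list with the other tested genes, and the median of all genes was 0.74, or 0.14 without receptor and clone-named genes. The list medians also depended on the scaling. They were -0.52, -0.57 and -0.31 after upper-quartile rescaling and -0.70, -1.03 and -0.66 after quantile normalization.

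The other lists did not pass in CD11b+ cells. Matrix and mesenchymal genes had 3 higher of 20 (5 over the list alone; camera adjusted p = 0.52), with Fn1 going from 1113 ± 530 to 5557 ± 3155 and the collagen gene Col3a1 from 164.1 ± 114.6 to 1393 ± 487. Col3a1 had adjusted p = 0.0486 by limma and was past the threshold in 10 of 24 alternatives. Lipid handling and cholesterol had 1 lower of 16, the cholesterol exporter Abca1, from 7026 ± 4077 to 1346 ± 702 (1 over the list alone; camera adjusted p = 0.14; log2 fold change -2.28 ± 0.60, and -5.79 ± 2.09 with adjusted p = 0.0995 after background subtraction), and immune checkpoint 1 lower of 12, Sirpa (1 over the list alone; camera adjusted p = 0.075). Cytokines and chemokines had 1 higher of 22, Spp1 (1 over the list alone; camera adjusted p = 0.59). Cell cycle, interferon response, pro-inflammatory macrophage, alternative macrophage activation and dissociation genes had none past the threshold by gene or over the list alone (camera adjusted p = 0.12, 0.85, 0.93, 0.5 and 0.33). The pro-inflammatory median was 1.41 while its test pointed down, and alternative activation had a median of -0.20 and a mean of 0.13. The interferon median of 0.55 was -0.07 after upper-quartile rescaling and -0.17 after quantile normalization, the erythroid one of 1.44 was -0.40 after the latter, and the lipid handling one of -0.24 was 0.08 in the FPKM table. Top2a, a mitotic topoisomerase, had 189.7 ± 96.5 in control and 1141 ± 377 in RasV12 cells (adjusted p = 0.0865). Hras fell from 415.2 ± 176.3 to 76.9 ± 111.0 (adjusted p = 0.0368, and 0.00185 to 0.171 over 24 alternatives, 15 of them past the threshold), while Nras and Msi1 did not pass (adjusted p = 0.787 and 0.685). The Hras call was lost without Control CD11b+ 1 or 3 or RasV12 CD11b+ 2 or 3 (adjusted p = 0.152, 0.128, 0.0976 and 0.0719).

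**Figure D3:**
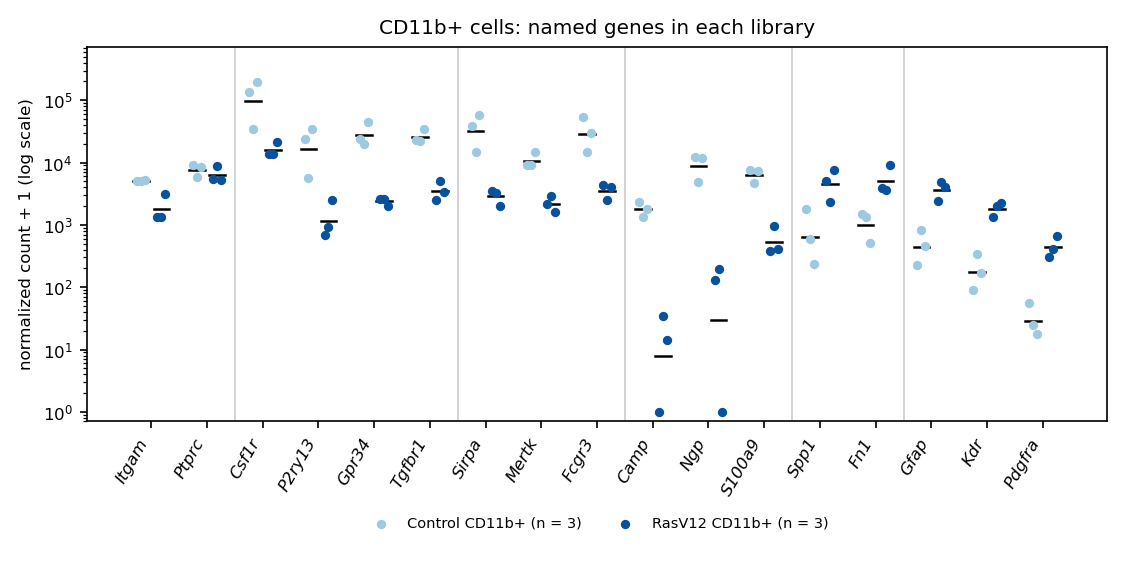
Normalized count + 1 on a log axis for 17 named genes in the CD11b+ libraries. Points are libraries, light blue for control and dark blue for RasV12, and bars are means of the log values; Ptprc overlapped between groups, while all RasV12 libraries lay below all control libraries for Sirpa, Camp and Ngp and above them for Gfap, Kdr and Pdgfra.

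The CD11b+ calls depended on the libraries and the scaling. In simulated data for this comparison false calls were more frequent than the threshold of 0.05 allows. Of 45 named genes called, 27 lost the call without at least 1 library, 23, 0 and 24 without Control CD11b+ 1, 2 and 3 and 15, 17 and 8 without RasV12 CD11b+ 1, 2 and 3. They were Abca1, B2m, Cd79b, Chst7, Col3a1, Ecscr, Efnb1, Elmo1, Fabp7, Fcgr3, Fn1, Gja1, Hras, Ifitm6, Kdr, Lcn2, Mertk, Ngp, Olfr1105, Olfr168, P2ry13, Pcp2, Pdgfra, S100a9, Slc2a1, Spp1 and Syt1, with adjusted p = 0.0513 to 0.212 where lost. The call was also lost by 28 of the 45 with edgeR, 23 of the 37 tested without the 2 shallowest RasV12 CD11b+ libraries, 10 without a filter, 6 after upper-quartile rescaling and all 45 in the fit of the 6 CD11b+ libraries alone. There were 307, 5390 and 356 calls without Control CD11b+ 1, 2 and 3 and 830 and 774 without RasV12 CD11b+ 1 and 2, against 1599 with all, and list calls fell from 10 to 5 without Control CD11b+ 1 and to 6 without RasV12 CD11b+ 2. The share of calls that were higher was 55.4%, against 29.6% after upper-quartile rescaling, 30.5% after quantile normalization and 6.9% of 434 calls with edgeR, and the median of all genes was 0.74, 0.19, 0.13 and 0.36. The share was 68.8% with a pseudocount of 5, 71.9% and 67.7% without Control CD11b+ 2 and 3, 32.4%, 32% and 36.7% without RasV12 CD11b+ 1, 2 and 3, 8.5% without the 2 shallowest RasV12 CD11b+ libraries, 41.8% with background subtracted and 38.9% without receptor and clone-named genes. A limma fit of these 6 libraries alone called 0 genes, with 6845 at an unadjusted p under 0.05, while DESeq2 called 2403 in the fit of all libraries. The fit of 6 rests on fewer libraries but takes its spread from CD11b+ cells alone, and Sirpa had adjusted p = 0.118 in it. Replicates correlated least in RasV12 CD11b+ cells, so the adjusted p from the spread of all 4 groups may be too small for CD11b+ cells.

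**Figure D4:**
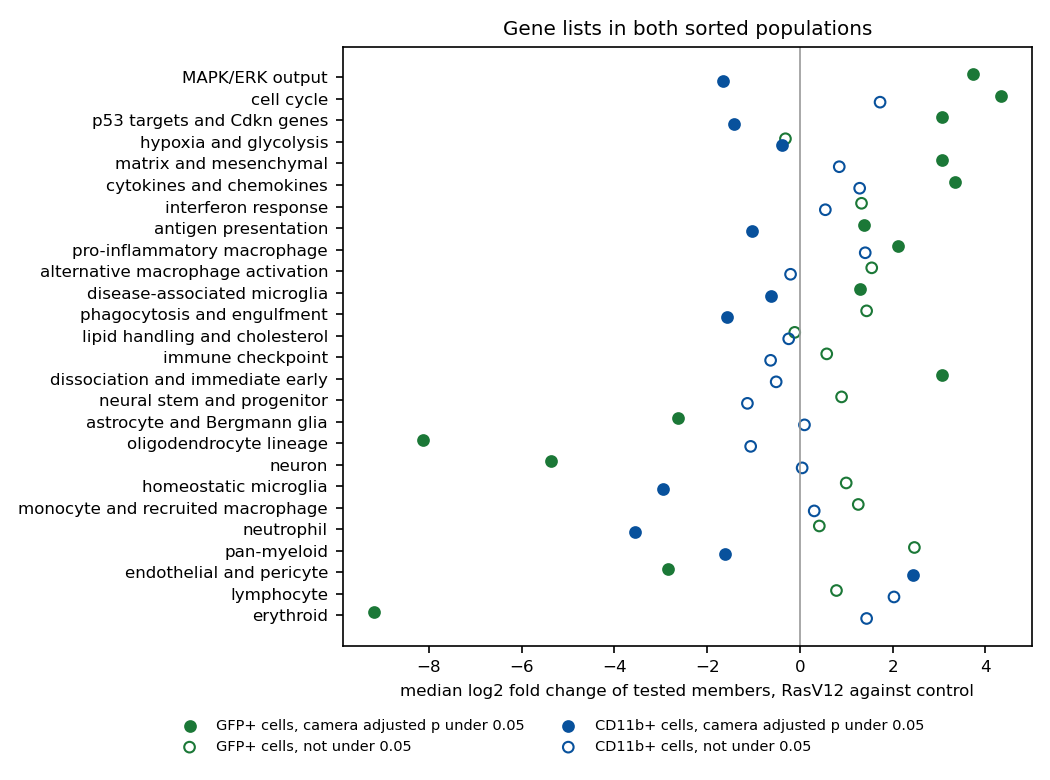
Median log2 fold change of each gene list, RasV12 against control, in GFP+ cells (green) and CD11b+ cells (blue). Filled points passed camera with its preset correlation and open points did not; the oligodendrocyte lineage median was -8.12 in GFP+ and -1.06 in CD11b+ cells, and the homeostatic microglia median 1.0 and -2.94.

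CD11b+ and GFP+ cells of the same tissue differed in the marker genes of the sort. In controls all 12 pan-myeloid genes were higher in CD11b+ cells (12 over the list alone; median 10.94, or 11.15 with unread groups at their bound; camera adjusted p = 9.9e-13), and 15 of 15 astrocyte and Bergmann glia genes were lower (15 over the list alone; median -6.07; camera adjusted p = 3.3e-24). The 5 higher genes with the largest change were Csf1r, Fcgr3, Gpr34, Ly86 and Fcrls, which had no read in Control GFP+ libraries and were at least 198700-fold, 45300-fold, 45360-fold, 26990-fold and 30710-fold higher. The lower ones included Tmem125, Kcnk1, Hba-a2 and Cend1. Tmem125 was at least 2879-fold lower, Kcnk1, a potassium channel, went from 3147 ± 140 to 2.5 ± 4.3, and the neuronal gene Cend1 from 2399 ± 726 to 5.7 ± 9.9. Hba-a2, a hemoglobin gene, was at 35496 ± 43973 in GFP+ and 45.4 ± 69.8 in CD11b+ cells. There were 5765 higher and 2061 lower genes, and 5198 calls in all without Control GFP+ 2. The higher share was 73.7%, against 86.3% after upper-quartile rescaling, 44.3% after quantile normalization and 63.1% with edgeR, with medians of all genes of 1.80, 2.31, -0.02 and 1.28. It was 46.4% with background subtracted, 47.9% after rescaling as well and 62.9% without receptor and clone-named genes.

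In RasV12 tumors 11 of 12 pan-myeloid genes (11 over the list alone; median 8.72; camera adjusted p = 3.7e-07) and 13 of 16 homeostatic microglia genes (15 over the list alone; median 8.47; camera adjusted p = 1.5e-05) were higher in CD11b+ than in GFP+ cells, and 1 homeostatic microglia gene was lower (1 over the list alone). MAPK/ERK output genes had 14 of 17 lower and 1 higher (15 and 1 over the list alone; camera adjusted p = 5.4e-11). The higher genes with the largest change were Tmem119, Lair1, Csf1r, Ccr1 and Laptm5. Tmem119, a microglia surface gene (chromosome 5, 113793729 to 113800516), the inhibitory receptor Lair1 and the chemokine receptor Ccr1 had no read in RasV12 GFP+ libraries and were at least 7421-fold, 10650-fold and 5425-fold higher. Csf1r had 16349 ± 4226 in CD11b+ and 9.4 ± 11.8 in GFP+ cells, and Laptm5 10851 ± 4314 and 10.4 ± 16.3. Nptx1, a neuronal pentraxin gene, Gal, Cdkn2b, Perp, a p53 effector gene, and Trp53i11 had no read in RasV12 CD11b+ libraries and were at least 14020-fold, 8524-fold, 7588-fold, 5917-fold and 5394-fold lower. There were 8896 higher and 3057 lower genes. Of the higher ones 4695 had predicted or clone names and 631 were receptor genes, against 12130 and 1095 of all 29835 tested. The higher share was 74.4%, against 44.7% after quantile normalization and 32.7% of 4692 calls with edgeR, with medians of all genes of 1.79, 0.30 and 1.08. It was 42.5% with background subtracted, 51.8% after rescaling as well, 53.2% without the 2 shallowest RasV12 CD11b+ libraries and 57.6% without receptor and clone-named genes.

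The RasV12 effect differed between CD11b+ and GFP+ cells at 1312 genes, 615 with a higher and 697 with a lower effect in CD11b+ cells. Klk6, a serine protease of oligodendrocytes, had 1611 ± 433 in control and 2.7 ± 3.1 in RasV12 GFP+ cells, and 12.5 ± 19.0 and 84.5 ± 7.6 in CD11b+ cells (difference 12.91 ± 1.69, adjusted p = 0.00142). Olfm3, Tbata, Ralyl and Lhx1os followed with differences of 12.90, 12.70, 12.53 and 12.37. Cd1d1 had no read in control and 159.0 ± 64.8 in RasV12 GFP+ cells, and 477.6 ± 89.0 and no read in CD11b+ cells (-16.13 ± 1.39, adjusted p = 3.67e-05). Chst7, Efnb1, the adaptor gene Fblim1 and Cdkn2b followed with -15.06, -14.22, -13.86 and -13.66. The count was 685, 630 and 697 without RasV12 GFP+ 1, 2 and 3 and 669, 2384 and 575 without Control CD11b+ 1, 2 and 3. The higher share of 46.9% was 19.1% after upper-quartile rescaling and 26.6% with edgeR, with medians of all genes of 0.07, -0.84 and -0.96, and 32.3% without the 2 shallowest RasV12 CD11b+ libraries.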

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

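The tests of paralogs, of DNA on more genes, of dilution, of recruited monocytes and of the numbers of the sexes, and the subtraction of background and the sex covariate, were chosen only after the result was seen. The RasV12 effect in CD11b+ cells minus that in GFP+ cells was tested by the interaction term of limma, and 71 of 110 named genes and 18 of 26 lists passed. Of the named genes, 10 were named for passing this same test and most others for their change in 1 population. Their share therefore follows from the naming. Over all genes 1312 of 29835 passed. In simulated data this test recovered 12.1% of 64-fold differences, so a gene that did not pass it can still differ.

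The named genes that rose in GFP+ cells and passed this test had a lower effect in CD11b+ cells, while Dhh, Aebp1, Cdc20, Cdk1, Slc16a3, Fn1, Tnc, Timp1 and Nes rose and did not pass it. Such a difference can come from the GFP+ change alone where CD11b+ cells have few or no reads. Gal, without reads in RasV12 CD11b+ libraries, changed by 11.96 in GFP+ cells. On the log2 scale the difference was -11.96 for Gal, -8.21 for Areg, -12.49 for Hpse, -8.74 for Psrc1, -10.55 for Chrdl1, -12.03 for Plau, -11.05 for Fam111a, -8.34 for Angpt2, -8.95 for Gdf15, -6.65 for Spp1, -9.05 for Ccl2 and -7.90 for Ptgs2. It was -5.91 for Ccnd1, -9.61 for Spry4, -11.89 for Fosl1, -8.47 for Cdkn2a, -13.66 for Cdkn2b and -11.04 for Pmaip1. Further ones had -3.05 for Ifitm3, -2.81 for B2m, -8.20 for Cd80, -7.71 for Cd274, -8.85 for Itgb2, -9.93 for Cd68, -7.70 for Itga4 and -4.66 for Tgfb1.

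Genes lower in RasV12 CD11b+ cells that passed had differences of -9.12 for Tmem167b, -16.13 for Cd1d1, -9.38 for Inafm1, -13.54 for Lcn2, -7.55 for Bag5, -8.20 for Gipc1, -14.22 for Efnb1, -15.06 for Chst7, -8.09 for Camp, -4.16 for Cd9 and -3.61 for Abca1. Fcgr3, also lower, had -7.70. Genes that did not pass in CD11b+ cells alone had differences of -13.86 for Fblim1, -6.18 for Gpr34, -9.69 for Tgfbr1 and -5.34 for Csf1r.

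The named genes that fell in GFP+ cells and passed this test had a higher effect in CD11b+ cells, while Ttr, Ntsr2, Fa2h, Slc2a1, Apoe, Sirpa, Cldn5, Sparc, Laptm5 and Pcp2 fell and did not pass it. A higher effect by this test need not be a rise in CD11b+ cells. Mog and Slco4a1 changed by -12.92 and -10.17 in GFP+ cells, close to their difference with the sign turned. The difference was 11.50 for Mog, 9.88 for Mal, 9.19 for Car8, 11.54 for Tspan2, 7.49 for Gjb1, 11.69 for Hapln2, 9.75 for Slco4a1, 12.91 for Klk6, 12.90 for Olfm3, 12.70 for Tbata, 12.53 for Ralyl and 12.37 for Lhx1os. It was 4.76 for Aldoc, 5.53 for S100b, 6.55 for Mbp, 4.90 for Snap25, 8.43 for Pvalb, 10.86 for Hbb-bs and 2.90 for Hmgcs1. Genes higher in RasV12 CD11b+ cells had 7.69 for Saa3, 7.38 for Crp, 7.58 for Peak1os, 7.12 for Tex24, 7.39 for Olfr66, 5.63 for Col3a1, 4.27 for Gfap, 2.94 for Gja1, 6.21 for Kdr and 5.43 for Syt1.

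Among lists the median difference was -5.91 for MAPK/ERK output, -3.80 for p53 targets and Cdkn genes, -2.42 for cytokines and chemokines, -2.66 for phagocytosis, -3.71 for homeostatic microglia, 6.65 for oligodendrocyte lineage, 5.38 for neuron and 5.52 for endothelial and pericyte genes, and these 8 held with an estimated correlation. Those that lost the call had -2.23 for cell cycle (adjusted p = 0.058 with an estimated correlation), -1.77 for matrix (adjusted p = 0.1), -2.50 for antigen presentation and -2.38 for pro-inflammatory genes (adjusted p = 0.11 for both), -2.04 for disease-associated microglia (adjusted p = 0.094) and -2.0 for dissociation genes (adjusted p = 0.41). The same holds for -3.52 for neutrophil and -3.21 for pan-myeloid genes (adjusted p = 0.072 for both), 2.36 for astrocyte (adjusted p = 0.079) and 9.95 for erythroid genes (adjusted p = 0.094). The pro-inflammatory median was 0.20 after background subtraction and rescaling.

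Comparisons of 3 against 3 libraries give too few splits for a share under 0.05. Every other split also mixes libraries of both real groups, so their difference enters the spread and lowers the count. The gap between real and other counts therefore does not decide whether chance gave the calls. The real counts and the highest of the other splits were 2027 and 0 genes and 14 and 12 lists in GFP+ cells, 1599 and 672 genes in CD11b+ cells, 11953 and 0 genes between populations in tumors, and 7826 and 0 in controls, each with 1 of 10 splits as large, the real one included. For CD11b+ lists 3 of 10 splits were as large, with 10 real and 11 in the highest other. Of 100 permutations of the RasV12 labels within each population, 2 gave as many interaction genes as the 1312, the real one included. The highest other gave 1608 and moved 0 labels in GFP+ and 4 in CD11b+ cells. Reversing the labels of 1 population, which was not among those drawn and adds both effects, gave 2499. Permuted labels also remove or reverse the RasV12 effects within each population, so these splits do not decide whether chance gave the difference.

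The RasV12 CD11b+ libraries and Control CD11b+ 2 had reads over olfactory receptor genes at 45.02 to 108.3 and over vomeronasal receptor genes at 22.37 to 53.43 normalized counts per kb of exon. Expression of the receptor genes was argued against, since other tissue-restricted families had at least 0.88 of the olfactory receptor density in every RasV12 CD11b+ library, and sharing of reads between paralogs, since TEC genes had at least 1.26 times that density. The ratios alone can pass without background, as Control GFP+ libraries had 22.28, 4.30 and 1.77 per kb for the families, TEC and olfactory receptor genes, not matched for GC. The families and TEC genes also rose, from 10.8 and 12.22 and from 13.48 and 15.11 in Control CD11b+ 1 and 3 to 66.51 ± 17.72 and 109.35 ± 21.48 in RasV12 CD11b+ libraries. Genomic DNA may be a source and stays open. The X to autosome ratio of RasV12 CD11b+ 3, which has Xist reads, was 2.84 times the mean of the 3 libraries with Y-linked reads, but over 15 X genes with a bootstrap interval of 0.11 to 3.36 for its ratio. Over 1334 X genes it was 1.4 times that mean but 1.27 times RasV12 CD11b+ 2 (0.86 against 0.67), less than was set for DNA against each library, and the bootstrap intervals of 0.71 to 1.04 and 0.52 to 0.83 overlap, so these ratios do not decide.

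Homeostatic microglia genes were lower in RasV12 CD11b+ cells by the preset test, with a median of -2.94, a call that was lost with an estimated correlation (adjusted p = 0.069). Dilution of all myeloid RNA by other template as the only cause stays undecided. These genes fell by 1.32 (SE 0.50) relative to pan-myeloid genes within a library, past the limit set against dilution after the result was seen. The exact two-sided permutation test gave p = 0.1, the smallest it allows, so it could not decide. The groups lay close, with 0.12 in Control CD11b+ 1 and 0.02 in RasV12 CD11b+ 2. Mean log2 values fell by 1.36 (SE 0.56) for pan-myeloid and 2.68 (SE 0.51) for homeostatic genes, so dilution may contribute and is not excluded. A total raised by background was argued against, since the median stayed at -2.51 after subtraction and rescaling, and at -2.66 in the version computed first. Replacement by recruited monocytes may contribute and cannot be told apart, since monocyte genes changed by 0.81 (SE 0.57, exact permutation p = 0.2) relative to pan-myeloid genes. A change of microglial state and the difference of tissue stay open, untested.

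In every group replicate 3 had reads on Xist, 2115 to 15293 normalized counts, and at most 7.2 on Y-linked genes, while replicates 1 and 2 had at most 22.2 on Xist. Unequal numbers of the sexes as a cause of the RasV12 calls were argued against, since the number of libraries with such Xist reads differed by 0 between RasV12 and control in both populations. With sex as a covariate the larger of the ratios of counts was 1.19, which decides nothing, since a covariate cannot move a fold in a balanced design. A RasV12 effect that differs between the sexes stays open, with 1 library of replicate 3 in each group.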

How the results depend on the processing

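Background subtraction, the sex covariate, leaving out Control CD11b+ 2 for its background or the 2 shallowest libraries, and leaving out receptor and clone-named genes were chosen only after the data were seen. The cause was not tested for any change below unless it is named. The pseudocount of 0.5, no filter, an added fold threshold and robust variance kept every count within 1.5 times. Depth limits RasV12 CD11b+ 1 and 2 most.

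Genes changed in GFP+ cells, 2027, became 1043 with quantile normalization, 4097 with array weights, 1122 with edgeR, 4907 with DESeq2, 1101 with background subtracted and 1021 after rescaling as well. Genes changed in CD11b+ cells, 1599, became 2522 with FPKM, 2421 with quantile normalization, 3542 with a pseudocount of 5, 3808 with array weights, 434 with edgeR, 2403 with DESeq2, 2447 with background subtracted, 5390 without Control CD11b+ 2, 532 without the 2 shallowest libraries and 967 without receptor and clone-named genes, where fewer genes were tested. With only the 6 libraries, limma called 0 (6845 at an unadjusted p under 0.05). CD11b+ against GFP+ cells gave, in tumors, 4692 with edgeR, 7639 and 7289 with background subtracted and rescaled, 3671 without the shallowest libraries and 6137 without receptor and clone-named genes, against 11953. In controls it gave 4104 with quantile normalization, 4613 with edgeR, 3674 and 3527 with background subtracted and rescaled and 5127 without those genes, against 7826. The difference of effects, 1312 genes, became 2446 with upper-quartile rescaling, 3102 with array weights, 3135 with DESeq2 and 2384 without Control CD11b+ 2. CD11b+ lists, 10, became 6 with a filter at 50, 3 with background subtracted, with or without rescaling, 3 without the shallowest libraries and 0 with camera's estimated correlation (5 at an unadjusted p under 0.05). Quantile normalization ended the CD11b+ calls of antigen presentation, disease-associated microglia and pan-myeloid genes (camera adjusted p = 0.32, 0.21 and 0.21), and after background subtraction and rescaling phagocytosis, homeostatic microglia and neutrophil genes stayed past the threshold.

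Leaving out 1 library gave 1005 to 1743 genes in GFP+ cells, 307 to 5390 in CD11b+ cells, 8093 to 12100 between populations in tumors, 5198 to 6521 in controls, 575 to 2384 for the difference of effects, and 13 to 16 and 5 to 11 lists. Without the 2 shallowest libraries the lone RasV12 CD11b+ library was assumed to vary like the other groups.

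Genes that reversed had not passed. In GFP+ cells Nras was at 0.14 with upper-quartile rescaling and Itgam at -0.79 with quantile normalization. In CD11b+ cells Ptprc was at 0.66 with quantile normalization. Msi1 was at 0.13 with array weights, 0.39 with DESeq2, 0.29 without Control CD11b+ 2, 0.10 without RasV12 CD11b+ 1, and 0.09 and 0.16 with background subtracted and rescaled. Nras was at 0.25 without RasV12 CD11b+ 1 and 0.59 without the shallowest libraries. Leaving out 1 library gave -0.63 to 0.25 for Nras and -3.95 to 0.29 for Msi1. Of 1135 planned values of named genes in GFP+ cells 1090 kept direction and side of the threshold, and of 1014 in CD11b+ cells 788.

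With the replicate block the counts were 1855, 1212, 11785, 7529 and 1173 genes and 14 and 10 lists, none moved by over 1.5 times. The block ended the CD11b+ calls of P2ry13, S100a9, Col3a1 and Ifitm6 (adjusted p = 0.0641, 0.0722, 0.0732 and 0.0699). With sex as a covariate the same genes lost the call (adjusted p = 0.0533, 0.0624, 0.0634 and 0.0595). The pairing check gave correlations of deviations from -0.029 to 0.09 between same-numbered libraries, and not every library correlated best with its own number.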

Other observations

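The genes below were chosen after their values were seen, all from the limma fit with its adjusted p. Hbegf, which encodes a ligand of the EGF receptor, stood at 18730 ± 7086 normalized counts in RasV12 and 1133 ± 734 in control GFP+ cells (log2 fold change 4.16 ± 0.63, adjusted p = 0.00169), and Ereg, which encodes another and had no read in control GFP+ cells, stood at 1519 ± 1369 (adjusted p = 0.00139). Lif, a cytokine of the interleukin-6 family, stood at 621.4 ± 205.1 and 0.5 ± 0.4 (adjusted p = 0.00367). Hmga2, a chromatin protein gene of embryonic tissue, stood at 913.6 ± 528.5 in RasV12 and 0.2 ± 0.3 in control GFP+ cells (adjusted p = 0.000283).

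Gbx2, a patterning gene of the hindbrain, stood at 438.9 ± 191.3 in RasV12 and 0.7 ± 0.8 in control GFP+ cells (adjusted p = 0.000475), En1, a midbrain and hindbrain patterning gene, at 68.7 ± 24.2 and 0.7 ± 1.2 (adjusted p = 0.0189), and Otx2, a forebrain and midbrain patterning gene, at 1.0 ± 1.7 and 435.4 ± 209.6 (adjusted p = 0.00375). Regional identity was not tested, and control GFP+ libraries also held reads of the choroid plexus gene Ttr. Serpine2, a protease inhibitor gene, rose in GFP+ cells from 7657 ± 1230 to 60827 ± 8644 (log2 fold change 2.99 ± 0.49, adjusted p = 0.00279) and fell in CD11b+ cells from 11467 ± 7353 to 836.7 ± 297.7 (-3.52 ± 0.49, adjusted p = 0.00332), with a difference of -6.51 (adjusted p = 0.000288).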
